A study of Homo sapiens with 28 samples.

How the data were processed

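The 28 libraries came from MDA-MB-453 cells given DMSO, JQ1, JQ1-VHL, IBET151 or IBET151-VHL for 3 h, with 0.1 mM 4-thiouridine for the last 60 min, and from a nuclear and a cytoplasmic fraction of each culture. Per the labels' protocols, 10% Drosophila S2 cells were added before digitonin, the 4-thiouridine was alkylated, ERCC RNA was added per mass of extracted RNA, and 3′ end libraries of polyadenylated RNA were sequenced as single reads of 100 bp. The labels' list of processing tools names bcl2fastq, Trimmomatic 0.39, HISAT2, HTSeq and DESeq2, without versions of the others, and the builds GRCh37, hg19 and dm3. How T>C reads were told from others is not given in these sources. No library without 4-thiouridine is in the series, so the background of T-to-C conversions is unknown.

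The authors deposited tables of all reads (16482 genes) and of T>C reads (13029 genes). These were analysed as deposited, as signal scaled by the authors to ERCC RNA. The values of each library were whole multiples of 1 step, the same in both tables. 100% of values lay within 0.001 of a whole read after division by it, so reads were recovered, 1 read being worth 0.670 to 2.24 units in the nuclear and 0.374 to 0.951 in the cytoplasmic libraries. The tables held no ERCC, Drosophila or mitochondrially encoded rows, so sums cover human nuclear genes only. Genes were matched by symbol through a gene table, and 479 and 245 genes without a symbol were tested but not named. Reads of near-identical copies, such as histone genes, may be shared between them. No coordinates are printed, and gene lengths were taken by Ensembl identifier from a newer annotation.

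Genes entered a fit with a value of at least 10 (all reads) or 5 (T>C reads) in at least 2 libraries. limma 3.58.1 (R 4.3.3), with a trend of variance on level, was fitted to log2(value + 1). 1 fit of the 14 libraries of a fraction gave each drug against DMSO and the compounds against each other. 1 fit of all 28 gave the nuclear minus the cytoplasmic drug effect and the DMSO fractions. Benjamini-Hochberg adjustment was per comparison, and a gene passed with an adjusted p under 0.05. Library sums and T>C shares were compared by 2-sided exact permutation tests, 36 in all, that permuted labels within the pairs of compounds where these were pooled. The interval of a difference between compounds is the 95% interval of the linear model.

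There were 20 gene lists, written before the files were seen: mRNA export factors, nuclear speckle and SR proteins, nuclear-retained RNAs, BET inhibitor response genes, polyadenylated histone genes, P-TEFb and elongation factors, BET proteins (not reported here), short-lived mRNAs, luminal and HER2 genes, ribosomal proteins, mitochondrially encoded genes (0 in either table, so not tested), ER-translated mRNAs, ribosome biogenesis and MYC targets, and genes of hypoxia, p53, heat shock, sterol synthesis, cell division, the interferon response, and stromal and immune cells. They were tested with limma's camera at a preset correlation of 0.01, against all other genes of the fit. Of the camera calls printed, those of the BET response genes in cytoplasmic reads of JQ1 and IBET151 and of the short-lived mRNAs against the parents held with an estimated correlation.

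Genes are named by a rule set beforehand: per comparison the 5 largest rises and falls with an adjusted p under 0.05, a mean of at least 50 (all reads) or 20 (T>C reads) and no overlap between groups; the 4 members of each list with the smallest p; and 11 genes in every comparison. FEZF1 and EPC1 fall outside it.

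Replicate numbers were checked by correlating the deviations of same-numbered libraries from their group means. The labels do not say what a number stands for, so pairing rests on this check, with every pair over 0.1 required. In all reads it held among DMSO, JQ1, JQ1-VHL and IBET151-VHL (lowest r 0.159 in the nucleus and 0.203 in the cytoplasm) and between the fractions of DMSO (0.105), and in T>C reads for nuclear JQ1 and DMSO (0.234).

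The alternatives were pseudocounts of 0.5 and 5, no filter or 1 at 5 times the minimum, median-ratio scaling over human genes, fits of only the groups compared, replicate or run of library numbers as a block, weights per library, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads with the deposited scaling kept, fry and camera with an estimated correlation for lists, and leaving out each library. A single gene was called reversed only where it passed in the main fit or in the alternative. In simulated data a shifted list was found (adjusted p = 4.78e-07 in all reads and 1.39e-12 in T>C reads), 0 unchanged lists were called, and of 12296 unchanged genes in all cytoplasmic reads 7 were called. In the real data 18 list tests lost a call with an estimated correlation, so the simulation cannot vouch for list calls. Figures used matplotlib 3.10.9 (Python 3.11.15).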

Results

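RNA was sequenced from MDA-MB-453 cells, a human breast cancer line, kept for 3 h in DMSO, in a BET bromodomain inhibitor (JQ1 or IBET151), or in a compound that links one of these inhibitors to a ligand of the ubiquitin ligase VHL (JQ1-VHL or IBET151-VHL) and is built to direct BET proteins to degradation. 4-thiouridine was present for 60 min, so that reads with T-to-C conversions (T>C reads) mark newly made RNA. Cells were parted with digitonin into a cytoplasmic supernatant and a nuclear pellet, and 3′ end libraries of polyadenylated RNA were read from each. There were 28 libraries in 10 groups, 3 per group, except 2 for IBET151 in each fraction. The doses are not in the labels. Each library held 17851589 to 38658448 reads in the nuclear groups and 30647584 to 68475299 in the cytoplasmic groups. Of these 214725 to 1928012 and 82264 to 379401 were T>C reads. The series asks how cells store and export new transcripts when transcription is briefly blocked. Each compound was set against DMSO in each fraction, compounds against each other, and nuclear against cytoplasmic effects. All values were scaled by the authors to spike-in RNA added per mass of RNA, so they give levels per RNA mass of a fraction and not per cell. Errors are standard deviations (SD) of levels or standard errors (SE) of log2 changes. P-values measure the spread between libraries (shared by all genes in nuclear T>C reads), which may be technical. Each library was left out in turn.

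New RNA fell most under the VHL compounds. In the cytoplasm T>C reads made up 0.782 ± 0.0355% (SD, n = 3) of all reads in DMSO, 0.544 ± 0.0215% in JQ1, 0.616 ± 0.0561% in IBET151 (n = 2), 0.288 ± 0.0221% in JQ1-VHL and 0.249 ± 0.0128% in IBET151-VHL. In the nucleus the shares were 5.54 ± 2.96%, 4.77 ± 2.49%, 4.61 ± 1.36%, 2.23 ± 0.272% and 1.38 ± 0.316% in the same order. The summed T>C value of the cytoplasm was 2.89-fold lower in JQ1-VHL than in DMSO and 3.26-fold lower in IBET151-VHL (2-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 libraries can give). In the nucleus it was 2.86-fold and 5.18-fold lower (exact p = 0.1 for each), the JQ1-VHL change of -1.52 log2 units being -0.85 without JQ1-VHL replicate 1. JQ1 and IBET151 changed it by -0.58 and -0.25 log2 units in the cytoplasm (exact p = 0.1 and 0.4) and by -0.53 and 0.073 in the nucleus (exact p = 0.3 and 0.9). IBET151 has no library in the first run of library numbers, so its nuclear change cannot be told from the run. Against their parents within each pair the VHL compounds changed the cytoplasmic sum by -1.20 log2 units (exact p = 0.005, Benjamini-Hochberg 0.06 over 36 tests) and the nuclear sum by -1.71 (exact p = 0.015, adjusted 0.09; exact p = 0.05 without any 1 of the IBET151-VHL replicates). All drugs together changed the cytoplasmic T>C share by -0.376 percentage points (exact p = 0.00275, adjusted 0.06). None of the 36 tests had an adjusted p under 0.05. The nuclear share differed between libraries of 1 group, being 8.02%, 6.34% and 2.25% in DMSO replicates 1 to 3. The difference of all drugs from DMSO there was -2.41 points (exact p = 0.102), or -1.17 without DMSO replicate 1 (exact p = 0.551), -4.05 without DMSO replicate 3 (exact p = 0.0256) and -2.77 without JQ1 replicate 1 (exact p = 0.035).

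**Figure D1:**
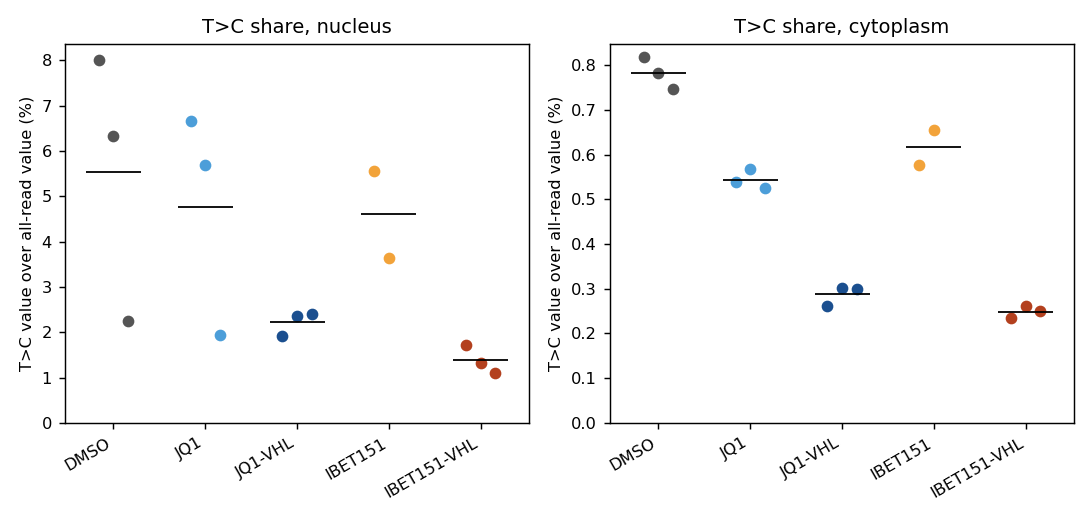
Share of T>C reads in percent of the summed value of each library, by treatment and fraction, with 1 point per library and a line at the mean of each group. Cytoplasmic shares lay between 0.235% and 0.818%, and nuclear shares between 1.10% and 8.02%.

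The summed value of all reads was near that of DMSO in the cytoplasm of every drug (log2 difference -0.085 in JQ1-VHL to 0.093 in IBET151, exact p = 0.7 and 0.6). 21 genes kept a T>C share in the cytoplasm under the VHL compounds at 0.8 to 1.25 times that in DMSO. They included SNX6 at 48.0%, TAFA2 at 95.6% and KDM5B at 22.8% in DMSO. Together they carried 20.2% of the summed cytoplasmic T>C value in DMSO and 61.0% under the VHL compounds. Without them the sum changed by -2.40 in JQ1-VHL and -2.93 in IBET151-VHL (log2; -1.53 and -1.71 with them), a larger fall that their choice by a constant share fixes. In the nucleus 8 of the 21 kept theirs, with SNX6 at 0.978 and TAFA2 at 0.999 times, as variants against the reference would. Only reads could tell these from new RNA.

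Among all cytoplasmic reads, JQ1 and IBET151 raised a set of known BET response genes. BRD2, itself a BET protein gene, stood at 7308 ± 1496 (SD, n = 3) in DMSO, 12862 ± 2750.4 in JQ1 (log2 change 0.82 ± 0.18 SE, adjusted p = 0.0156) and 13578 ± 71.3 in IBET151 (n = 2, 0.92 ± 0.20, adjusted p = 0.0231). HEXIM1, whose protein holds the elongation kinase P-TEFb inactive, stood at 2525 ± 745 in DMSO and 4253 ± 955 in JQ1, a change that did not pass (0.77 ± 0.23, adjusted p = 0.071) but did with median-ratio scaling (0.93), with the replicate or the run of library numbers as a block, with DESeq2 (0.75), and without DMSO replicate 2 (0.99). BRD2 did not pass without JQ1 replicates 1 or 2 (0.66 and 0.83) in JQ1, nor without IBET151 replicates 1 or 2 (0.92 and 0.91) in IBET151, nor in either with only the groups compared. The largest rises were TUBB3 (a neuronal tubulin), from 13.4 ± 8.04 to 161 in JQ1 (3.60) and 228 in IBET151 (4.16), and the signalling genes SOCS1, RGS2 and DYRK3 in both drugs (2.96, 2.95 and 2.92 in JQ1). The zinc-finger gene ZNF689 fell from 909 ± 209 to 153 in JQ1 (-2.55 ± 0.27, adjusted p = 1.60e-04) and by 6.16-fold in IBET151. MYC, a growth regulator, was at 171 ± 88.3 in DMSO, 71.6 ± 18.7 in JQ1 (-1.10 ± 0.48, adjusted p = 0.273) and 78.8 in IBET151 (adjusted p = 0.439), neither passing.

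Of 12470 genes tested in the cytoplasm, 102 rose and 499 fell in JQ1, and 112 rose and 202 fell in IBET151. With median-ratio scaling the splits were 254 higher and 499 lower in JQ1, where the median of all genes moved from -0.13 to 0.025, and 218 and 415 in IBET151. Replicate numbers paired the samples of JQ1 and DMSO in this table, and with a replicate block 152 and 796 genes rose and fell in JQ1. The JQ1 count was 273 and 318 without JQ1 replicates 2 and 3, and 953 without DMSO replicate 3. The IBET151 count was 203 and 532 without DMSO replicates 1 and 2, and more genes rose than fell without DMSO replicate 2. In the list of 12 tested genes known to rise after BET inhibition, 7 rose and 0 fell in JQ1 (9 and 0 adjusted over the list alone), among them BRD2 and the histone gene H2BC21 (1.34), and 5 rose and 0 fell in IBET151 (9 and 0 alone). The median change was 0.89 and 0.96 (limma's camera, adjusted p = 8.45e-18 and 2.87e-12, or 0.0132 and 0.0456 with an estimated correlation). Of 20 polyadenylated histone genes, 7 rose and 0 fell in JQ1 (10 and 0 alone) with a median of 0.54 (adjusted p = 3.04e-14, 0.154 with estimated correlation), and 4 rose and 0 fell in IBET151 (9 and 0 alone). Of short-lived mRNAs, 5 rose and 5 fell of 43 tested in JQ1 (9 and 6 alone). Of 19 p53 targets 4 rose and 1 fell in JQ1 (5 and 3 alone). In a simulation of JQ1-VHL in this table with 12496 genes, 8 of 67 genes changed 1.5-fold, 29 of 67 changed 2-fold and 65 of 66 changed 4-fold were recovered.

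The VHL compounds instead lowered short-lived mRNAs in the cytoplasm. MYC fell from 171 ± 88.3 in DMSO to 7.18 ± 3.22 in JQ1-VHL (n = 3, -4.29 ± 0.48, adjusted p = 5.33e-05) and 10.0 ± 2.90 in IBET151-VHL (-3.82 ± 0.48, adjusted p = 6.51e-05). It differed from the parent compounds by -3.19 and -2.75 log2 units (adjusted p = 0.00106 and 0.00457). HEXIM1 fell to 1361 ± 293 in JQ1-VHL and 1399 ± 179 in IBET151-VHL (adjusted p = 0.0189 and 0.0221), a change of -1.64 and -1.61 from the parents (adjusted p = 4.80e-04 and 9.39e-04). Its fall did not pass without JQ1-VHL replicate 1 (-0.68) or DMSO replicate 2 (-0.65) in JQ1-VHL, nor without IBET151-VHL replicates 1 or 3 (-0.71 and -0.84) or DMSO replicate 2 (-0.59) in IBET151-VHL, nor in either with weights per library or only the groups compared. The difference of MYC from IBET151 did not pass without IBET151 replicate 2 (-2.09). BRD2 stood at 5959.7 and 6045, with changes of -1.09 and -1.17 from the parents (adjusted p = 0.00183 and 0.00156). Its fall from DMSO passed only with the run as a block (-0.40 and -0.38) and without the last run (run D; -0.45 and -0.44). SPRY1, a brake on growth factor signalling, fell from 643 ± 79.7 to 53.3 in JQ1-VHL and 38.4 in IBET151-VHL, and DUSP6, a phosphatase of the same pathway, fell from 3944 ± 665 to 296 in IBET151-VHL. Against the trend EGR1 and FOS, immediate-early factors of that pathway, rose, EGR1 from 436 ± 199 to 7230.4 ± 4364 in JQ1-VHL (3.90 ± 0.67, adjusted p = 0.00129), and FOS from 27.5 ± 4.78 to 237 (2.80, not passing with weights per library).

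**Figure D2:**
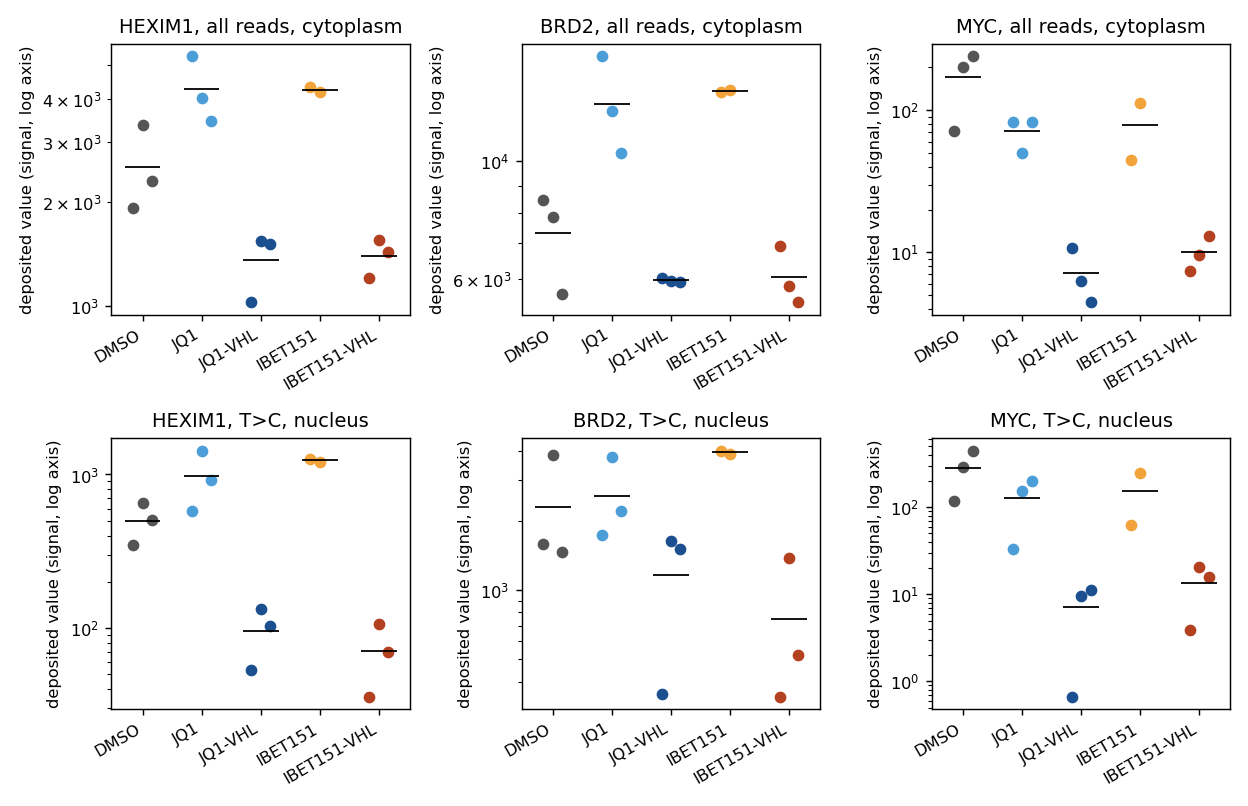
Deposited value per library on a log axis for HEXIM1, BRD2 and MYC, with all reads of the cytoplasm in the top row and T>C reads of the nucleus in the bottom row, by treatment, with 1 point per library and a line at the group mean. Cytoplasmic HEXIM1 averaged 4253 in JQ1 and 1361 in JQ1-VHL.

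In JQ1-VHL 52 of 12470 cytoplasmic genes rose and 1556 fell, and in IBET151-VHL 58 rose and 1916 fell. Median-ratio scaling gave 231 higher and 1173 lower, and 488 and 1619, moving the median of all genes from -0.17 to 0.048 and from -0.15 to 0.066. The JQ1-VHL count was 905 without JQ1-VHL replicate 1. Of 43 short-lived mRNAs 2 rose and 26 fell in JQ1-VHL (2 and 29 adjusted over the list alone) and 2 rose and 26 fell in IBET151-VHL (3 and 28 alone), such as SOX9, a lineage factor (-2.62 and -2.69), and DUSP4 (-2.96 and -3.16). Relative to the median of all genes the list's median was -1.12 and -1.16 (camera, adjusted p = 4.03e-13 and 5.06e-10, or 0.468 and 0.576 with estimated correlation). Against the parents 32 and 33 members were lower and 0 higher in either pair (adjusted p = 1.80e-44 and 8.92e-31, or 0.0137 and 0.0465 with estimated correlation). Of 19 p53 targets 10 fell in each VHL compound (11 and 10 alone), among them PLK2 (-3.30 and -3.42) and the cell death gene BBC3 (-1.38 and -1.19). The camera p for these targets was 6.52e-06 and 4.61e-04, or 0.6 and 0.576 with estimated correlation. Of 12 BET response genes 0 rose and 1 fell in JQ1-VHL (1 and 1 alone) and 0 rose and 2 fell in IBET151-VHL (4 and 2 alone). Of these genes 3 and 3 were lower than in the parents (8 and 4 alone; camera, adjusted p = 3.59e-09 and 6.51e-04, or 0.0634 and 0.378 with estimated correlation). Of 34 mRNA export factors 3 fell in JQ1-VHL and 6 in IBET151-VHL (3 and 6 alone), among them NXT1, the partner of the export receptor NXF1 (-0.91 and -1.53), and the nuclear pore gene NUP153 (-1.56 and -1.51). The fall of NXT1 in JQ1-VHL did not pass with median-ratio scaling (-0.69), nor without JQ1-VHL replicate 1 (-0.81) or DMSO replicate 2 (-0.76), nor with only the groups compared. Of 33 speckle and SR protein genes 6 and 5 fell (6 and 5 alone), such as RBM39 (-1.01 and -1.01).

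In the other lists, for all cytoplasmic reads in the order JQ1, JQ1-VHL, IBET151 and IBET151-VHL, 4, 7, 2 and 6 of 32 luminal and HER2 genes fell (4, 8, 4 and 6 adjusted over the list alone). GATA3, a luminal lineage factor, fell by 3.61-fold in JQ1-VHL and 4.24-fold in IBET151-VHL (adjusted p = 1.66e-05 and 2.15e-06), while ERBB2, the HER2 gene, did not pass in either (0.16 and 0.27). Of 29 P-TEFb and elongation factor genes 2, 6, 1 and 6 fell (2, 6, 1 and 6 alone), with HEXIM2 at -1.73 in JQ1 and -1.92 in IBET151-VHL. Of 33 ribosome biogenesis and MYC target genes 3, 7, 2 and 8 fell (3, 8, 3 and 8 alone), and of 20 hypoxia genes 1, 5, 0 and 4 (1, 5, 0 and 4 alone). Of 16 heat shock and unfolded protein genes 1, 4, 1 and 4 fell (1, 5, 1 and 4 alone), and of 19 interferon response genes 0, 3, 0 and 1 (0, 5, 0 and 1 alone). Of 29 cell division genes 0, 1, 0 and 1 fell (0, 1, 0 and 1 alone). Of 6 nuclear-retained RNAs none rose and 0, 0, 0 and 1 fell. None of 77 ribosomal protein, 41 ER-translated, 19 sterol synthesis and 4 stromal or immune marker genes passed in any drug by limma or edgeR. Over the 4 drugs their tests had an unadjusted p under 0.05 in 2, 1, 3 and 0 cases, and DESeq2 called 0, 1, 0 and 0.

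Among all nuclear reads TEX14, a gene of germ cell division, rose from 93.4 in DMSO (n = 3) to 2054 ± 1019.8 (SD) in JQ1 (4.36 ± 0.70, adjusted p = 2.27e-04) and 2199 in IBET151 (n = 2, 4.48), which did not pass without IBET151 replicate 1 (3.97) or with nuclear numbers 2 and 3 alone. SERPINI1, a protease inhibitor on the list of BET response genes, rose from 28.3 to 279 in IBET151 (3.31 ± 0.73, adjusted p = 0.0319). It did not pass without DMSO replicates 1 or 2 (2.98 and 3.47) or IBET151 replicates 1 or 2 (3.12 and 3.51), nor without a filter, with only the groups compared, or with numbers 2 and 3 alone. The VHL compounds raised DRC1, a gene of the ciliary motor, from 6.69 ± 3.55 to 229 in JQ1-VHL (4.87 ± 0.66, adjusted p = 7.42e-07) and 235 in IBET151-VHL, and TP53AIP1, a cell death gene, by 4.44 and 4.61. MYC fell from 556 ± 372 to 25.3 ± 15.0 in JQ1-VHL (-4.41 ± 0.71, adjusted p = 3.29e-05) and 27.2 in IBET151-VHL, and the cell cycle factor FOXM1 fell by 25.5-fold in IBET151-VHL. NEAT1, a noncoding RNA that builds paraspeckles, averaged 13414 in DMSO, 19358 in JQ1, 27172 in JQ1-VHL, 26119.7 in IBET151 and 24426 in IBET151-VHL, and passed in none (adjusted p = 0.572 at the lowest). It did pass in JQ1-VHL and IBET151-VHL with median-ratio scaling (1.42 and 1.66), a replicate block, which pairs them with DMSO, the run as a block and weights per library. In JQ1 it passed with the run as a block (0.56) and weights (0.43), and in IBET151 with a replicate block across runs (1.19). Both did with scaling and replicate block together (1.01 and 0.84).

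Of 14417 nuclear genes, 3 rose and 7 fell in JQ1, 130 and 154 in JQ1-VHL, 13 and 1 in IBET151, and 128 and 528 in IBET151-VHL. The median of all genes lay at -0.43, -0.48, 0.054 and -0.71. Median-ratio scaling gave 291 higher and 327 lower, 404 and 879, 251 and 323, and 738 and 1366, turning the balance of IBET151. Replicate numbers paired DMSO with JQ1 and with both VHL compounds here, and a replicate block gave 162 and 1376, 378 and 3379, and 330 and 6300 higher and lower genes in JQ1, JQ1-VHL and IBET151-VHL. The JQ1 count was 16, 3 and 4 without DMSO replicates 1, 2 and 3, and 4, 2 and 34 without JQ1 replicates 1, 2 and 3. More genes rose than fell without JQ1 replicate 1 or DMSO replicates 2 or 3. For JQ1-VHL it was 163 and 145 without JQ1-VHL replicates 1 and 3, and 155 and 137 without DMSO replicates 2 and 3, and more genes rose than fell without JQ1-VHL replicate 1 or DMSO replicates 2 or 3. For IBET151 it was 8 and 9 without DMSO replicates 1 and 2. For IBET151-VHL it was 307 without IBET151-VHL replicate 1, and 279 and 302 without DMSO replicates 2 and 3. Of 12 BET response genes 0, 0, 1 and 0 rose in the same order (1, 2, 4 and 2 adjusted over the list alone). Their median lay at 1.08 in JQ1 and 1.56 in IBET151 (camera, adjusted p = 1.03e-18 and 1.07e-14, or 0.308 and 0.539 with estimated correlation). Of 43 short-lived mRNAs 6 and 9 fell in JQ1-VHL and IBET151-VHL (16 and 20 alone). None of 34 export factors or 33 speckle genes passed in any drug by limma, where 3 and 1 of their tests over the 4 drugs had an unadjusted p under 0.05 and edgeR called 1 and 0. In a simulation of JQ1 in this table with 14336 genes and no block, 0 of 67 genes changed 2-fold and 2 of 66 changed 4-fold were recovered.

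Newly made RNA in the nucleus fell for most genes under the VHL compounds. TFAP2B, a luminal transcription factor, fell from 1272 ± 425 T>C units in DMSO (SD, n = 3) to 44.8 in JQ1, 34.3 in JQ1-VHL, 37.1 in IBET151 (not passing with numbers 2 and 3 alone) and 4.69 ± 4.37 in IBET151-VHL (-8.28 ± 0.76, adjusted p = 1.67e-23). ERBB2 fell from 824 to 137 in JQ1-VHL (-2.59) and 54.5 in IBET151-VHL (-3.76). HEXIM1 averaged 499 ± 151 in DMSO, 978 in JQ1 and 1239 in IBET151, neither passing, and fell to 95.9 in JQ1-VHL (-2.42 ± 0.68, adjusted p = 0.00184) and 70.2 in IBET151-VHL (-2.90, but 0.092 and not passing with median-ratio scaling). In JQ1 its rise did pass with that scaling (1.51), the run as a block (0.92) and weights per library (0.83), and in IBET151 with weights (1.76) and with scaling and replicate block together (1.41). MYC fell from 285 ± 166 to 7.08 in JQ1-VHL (-5.38 ± 0.77, adjusted p = 2.28e-09) and 13.4 in IBET151-VHL. Against this fall the linker histone gene H1-2 rose by 3.65 and 3.56, and THEMIS, known as a T cell gene, rose from 2.79 to 94.1 and 139.7. Median-ratio scaling left the falls of HEXIM1 (-0.66) and ERBB2 (-0.83) in JQ1-VHL and of MYC in IBET151-VHL (-1.48) not passing. NXF1, the main mRNA export receptor, passed in none of the drugs (1.38, -0.059, 2.12 and -0.36 in JQ1, JQ1-VHL, IBET151 and IBET151-VHL), while with median-ratio scaling it rose and passed in all 4 (1.96, 1.69, 2.10 and 2.63). With the run as a block it passed as a rise in JQ1 (1.38) and as a fall in IBET151-VHL (-0.99), and with weights as a rise in JQ1 (1.11) and IBET151 (2.05).

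Of 12059 genes with nuclear T>C reads, 15 rose and 276 fell in JQ1, 154 and 7290 in JQ1-VHL, 38 and 119 in IBET151, and 132 and 10116 in IBET151-VHL. The median of all genes was -0.67, -1.92, -0.069 and -3.12. Median-ratio scaling gave 98 higher and 114 lower, 717 and 908, 89 and 94, and 1714 and 3193. IBET151 lacks the first run of library numbers here too, and the main fit held no run. As all genes share a spread here, these counts say less about the shift of whole libraries than the library sums do. With a replicate block, which pairs JQ1 and DMSO here, 31 and 491 genes rose and fell in JQ1. The JQ1 count was 175 and 90 without DMSO replicates 1 and 2, and 117 and 105 without JQ1 replicates 1 and 3. The counts of JQ1-VHL were 3828 without JQ1-VHL replicate 1 and 3643 without DMSO replicate 2. Those of IBET151 were 97 and 95 without DMSO replicates 1 and 2. Of 34 mRNA export factors 18 fell in JQ1-VHL and 31 in IBET151-VHL (16 and 31 adjusted over the list alone), such as ALYREF, the adaptor that loads NXF1 (-2.13 and -4.04), and RBM15 (-3.23 and -5.85). Of 33 speckle and SR protein genes 14 and 33 fell (13 and 33 alone), such as the splicing factor SRSF1 (-2.75 and -5.20). With median-ratio scaling ALYREF (-0.40 and -1.27) passed in neither, and RBM15 (-1.52) and SRSF1 (-1.03) did not in JQ1-VHL, where ALYREF also did not pass without JQ1-VHL replicate 1 (-1.66) or DMSO replicate 2 (-1.70) or with weights, nor ALYREF and SRSF1 with numbers 2 and 3 alone. Relative to the median of all genes the export list moved by 0.20 and -0.12 and the speckle list by 0.51 and 0.42 (camera, adjusted p = 0.556 and 0.353, and 0.706 and 0.41). With median-ratio scaling both lists lay above other genes in JQ1-VHL (adjusted p = 0.0316 and 0.00974). In JQ1 and IBET151 0 members of either passed by limma (4 tests with an unadjusted p under 0.05, 0 called by edgeR). Of 12 BET response genes, 1 rose and 0 fell in JQ1 (6 and 0 alone) and 4 rose and 0 fell in IBET151 (10 and 0 alone), while 6 rose and 1 fell in JQ1-VHL (6 and 1 alone) and 6 rose and 4 fell in IBET151-VHL (6 and 4 alone). Their median stood 3.69 and 4.64 above that of all genes in the VHL compounds (adjusted p = 4.44e-18 and 8.27e-16, or 0.144 and 0.185 with estimated correlation). Of 19 polyadenylated histone genes, 8 rose and 0 fell in JQ1-VHL (7 and 0 alone) and 7 rose and 3 fell in IBET151-VHL (7 and 3 alone), among them H1-2 and H2BC4 (3.62 and 3.67).

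In the other lists the part of genes that fell in nuclear T>C reads varied. In JQ1-VHL and IBET151-VHL 23 and 27 of 30 luminal and HER2 genes fell (23 and 27 adjusted over the list alone), with a median of -0.50 and -0.52 relative to all genes (camera, adjusted p = 0.0199 and 0.0376, or 0.929 and 0.884 with estimated correlation). Of 43 short-lived mRNAs 21 and 25 fell (21 and 25 alone), and of 29 P-TEFb and elongation genes 19 and 27 (19 and 27 alone) with NELFCD, a pausing factor, at -7.17 in IBET151-VHL. Of 32 ribosome biogenesis and MYC targets 26 and 31 fell (26 and 31 alone). Of 76 ribosomal protein genes 8 and 39 fell (0 and 31 alone), and of 42 ER-translated mRNAs 28 and 39 (28 and 39 alone). Of 29 cell division genes 11 and 27 fell (8 and 27 alone), and of 19 sterol synthesis genes 6 and 11 (1 and 11 alone). Of 21 hypoxia genes 16 and 18 fell (16 and 18 alone), and of 18 p53 targets 16 and 17 (16 and 17 alone). Of 16 heat shock genes 7 and 11 fell (6 and 11 alone), and of 18 interferon response genes 16 and 16 (16 and 16 alone). Of 6 nuclear-retained RNAs 1 and 3 fell (1 and 3 alone), with MALAT1 at 995 in DMSO, 1708 in JQ1-VHL and 1266 in IBET151-VHL. Neither passed, though MALAT1 rose by 1.89 and 3.09 and passed with median-ratio scaling, as in JQ1-VHL with weights (1.24), and fell by 1.03 and 1.08 and passed with the run as a block. Of 3 stromal or immune markers 1 and 1 fell (1 and 1 alone).

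**Figure D3:**
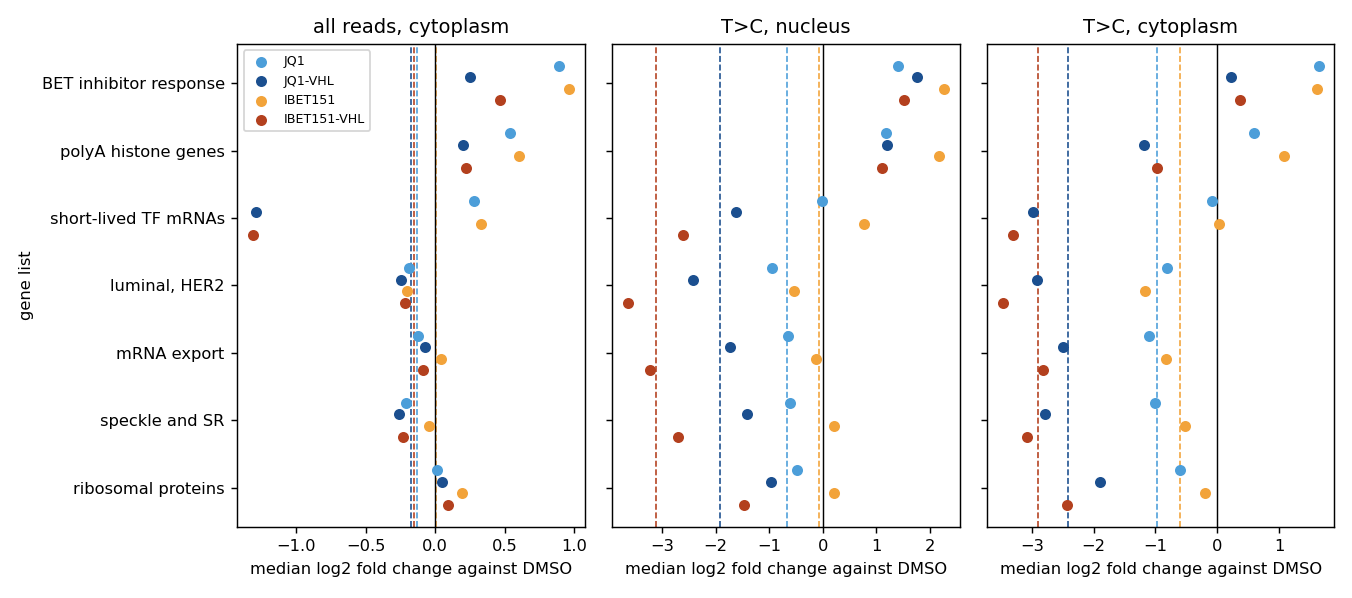
Median log2 change from DMSO of 7 gene lists by drug, for all reads of the cytoplasm, T>C reads of the nucleus and T>C reads of the cytoplasm, with dashed lines at the median of all genes for each drug. In nuclear T>C reads under IBET151-VHL the BET response list lay at 1.53 and the median of all genes at -3.12.

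Under the VHL compounds long genes lost less new RNA than short ones. Nuclear T>C values of genes of 200 kb or more had a median change of -1.36 in JQ1-VHL and -2.26 in IBET151-VHL, and those of genes under 20 kb -2.09 and -3.24.

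**Figure D4:**
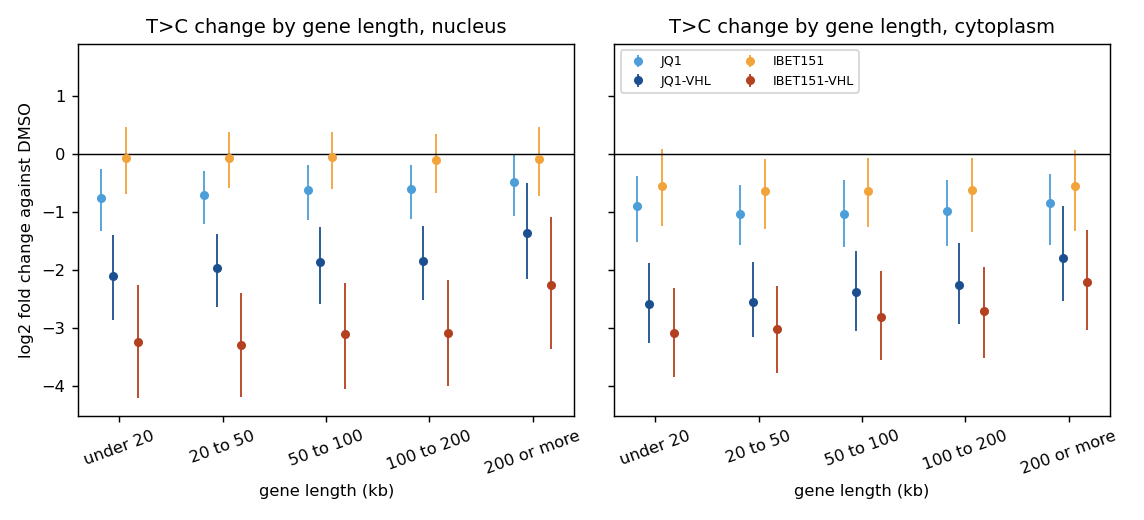
Median T>C change from DMSO, log2, by bin of gene length in kb, with bars from the lower to the upper quartile, for the 4 drugs in nucleus and cytoplasm. Nuclear medians went from -3.24 for genes under 20 kb to -2.26 for genes of 200 kb or more under IBET151-VHL.

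Newly made RNA that had reached the cytoplasm fell for most genes as well. GATA3 fell from 1558 ± 299 in DMSO (SD, n = 3) to 102 ± 26.2 in JQ1-VHL (-3.93 ± 0.27, adjusted p = 1.50e-11) and 42.6 ± 6.49 in IBET151-VHL (-5.15). HEXIM1 fell from 75.5 ± 22.4 to 3.73 (-4.11 ± 0.48, adjusted p = 1.13e-07) and 1.29 (-5.13), while JQ1 left it at 65.2 and IBET151 at 96.4 (neither passing). BRD2 fell from 193 to 42.1 (-2.23) and 23.1 (-2.99), but did not pass with median-ratio scaling (-0.035 and -0.051). TFAP2B fell from 133 ± 47.0 to 1.44 in JQ1 (-5.74 ± 0.58, adjusted p = 3.99e-07) and 4.20 in IBET151. RRS1, a ribosome assembly gene, averaged 95.7 ± 10.6 in DMSO and was listed at 0 in every JQ1-VHL library. EGR1 rose from 85.6 ± 45.8 to 399.6 in JQ1, 563 in JQ1-VHL, 687 in IBET151 and 709 in IBET151-VHL (adjusted p = 0.00179, 2.20e-05, 0.00108 and 3.20e-06; not passing in IBET151 without IBET151 replicate 2 (2.22)), and FOS rose in all 4 drugs.

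Of 6300 genes with cytoplasmic T>C reads, 31 rose and 1264 fell in JQ1, 12 and 5214 in JQ1-VHL, 33 and 426 in IBET151, and 10 and 5561 in IBET151-VHL. The median of all genes was -0.97, -2.42, -0.60 and -2.89. After median-ratio scaling the splits were 20 higher and 17 lower, 170 and 710, 12 and 10, and 399 and 1633, turning the balance of JQ1 and IBET151. The JQ1 count was 750 and 513 without DMSO replicates 1 and 2, and 636 without JQ1 replicate 3. The IBET151 count was 269 and 231 without DMSO replicates 1 and 2. Of 28 export factors 4, 22, 1 and 23 fell in JQ1, JQ1-VHL, IBET151 and IBET151-VHL (3, 22, 1 and 23 adjusted over the list alone), with NUP153 at -2.66 in JQ1 (-1.87 and not passing with median-ratio scaling) and -4.30 in JQ1-VHL. Of 32 speckle and SR protein genes 8, 30, 0 and 32 fell (9, 30, 0 and 32 alone), such as the splicing factor SRSF6 (-3.17 in JQ1-VHL, or -1.06 and not passing with that scaling, and -4.08 in IBET151-VHL). The export list's median stood at -0.071 and 0.081 relative to all genes under the VHL compounds, and that of the speckle list at -0.37 and -0.18. Of 11 BET response genes, 6 rose and 0 fell in JQ1 (7 and 0 alone) and 4 rose and 0 fell in IBET151 (6 and 0 alone), with medians of 1.64 and 1.62 (camera, adjusted p = 6.87e-17 and 2.75e-13, or 0.00964 and 0.0224 with estimated correlation). Under the VHL compounds 1 rose and 4 fell in JQ1-VHL (1 and 3 alone) and 2 rose and 3 fell in IBET151-VHL (1 and 3 alone). Of 17 polyadenylated histone genes, 6 rose and 0 fell in JQ1 (6 and 0 alone) and 1 rose and 9 fell in JQ1-VHL (1 and 8 alone), where the list's median of -1.19 lay 1.23 above that of all genes. Of 73 ribosomal protein genes 62 and 66 fell under the VHL compounds (62 and 66 alone), though relative to all genes their median was 0.53 and 0.46. In a simulation of JQ1-VHL in this table with 7601 genes, 1 of 67 genes changed 2-fold and 37 of 66 changed 4-fold were recovered.

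In T>C reads more genes were lower than higher in each VHL compound than in its parent. MYC in nuclear T>C reads was 7.08 in JQ1-VHL and 128 in JQ1 (-4.09 ± 0.77, adjusted p = 1.75e-04), and 13.4 in IBET151-VHL and 156 in IBET151 (-3.38, or -0.50 and not passing with median-ratio scaling, nor without IBET151 replicate 2 (-2.39)). HEXIM1 changed by -3.34 ± 0.68 (adjusted p = 4.14e-04) and -4.25 ± 0.76 (adjusted p = 6.13e-07) in the nucleus, and by -3.94 and -5.49 in the cytoplasm. THEMIS ran the other way, at 139.7 ± 69.5 in IBET151-VHL and 7.04 ± 7.14 in IBET151 (4.37 ± 0.97, adjusted p = 3.39e-05). NXF1 was lower in IBET151-VHL than in IBET151 (122 and 613, -2.48 ± 0.76, adjusted p = 0.00198), but 0.53 and not passing with median-ratio scaling, and not passing without IBET151 replicate 1 (-2.14). Between the VHL compounds, the cell cycle brake RBL2 was at 45.8 ± 27.5 nuclear T>C units in JQ1-VHL and 1.55 ± 2.69 in IBET151-VHL (4.47 ± 0.80, adjusted p = 9.76e-05). Cytoplasmic T>C values of GATA3 and DUSP6 were higher in JQ1-VHL by 1.22 and 1.77. Neither passed with median-ratio scaling (0.47 and 1.12) or a pseudocount of 5, nor GATA3 without JQ1-VHL replicate 2 (1.03). In all cytoplasmic reads EPC1, a histone acetyltransferase subunit gene named here after its values were seen, was at 1163 ± 156 in JQ1-VHL and 427 ± 42.8 in IBET151-VHL (1.44 ± 0.19, adjusted p = 0.0205). It did not pass with only the groups compared, nor without IBET151-VHL replicates 1, 2 or 3 (1.43, 1.51 and 1.37) or JQ1-VHL replicates 2 or 3 (1.36 and 1.40).

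In nuclear T>C reads 40 genes were higher and 1563 lower in JQ1-VHL than in JQ1, and 36 higher and 9815 lower in IBET151-VHL than in IBET151. In cytoplasmic T>C reads the counts were 8 and 2927, and 3 and 4352. With median-ratio scaling the splits were 170 higher and 234 lower, and 719 and 1187, in the nucleus and 49 and 170, and 192 and 624, in the cytoplasm. The shift taken out was -1.17 and -3.01 in the nucleus and -1.39 and -2.25 in the cytoplasm. The nuclear JQ1-VHL count was 1022, 105 and 964 without JQ1 replicates 1, 2 and 3, and 402 and 2579 without JQ1-VHL replicates 1 and 2. JQ1-VHL exceeded IBET151-VHL in 1325 nuclear genes and fell short in 1 (472 higher and 151 lower with median-ratio scaling), and in 191 and 1 cytoplasmic genes (127 and 28 with that scaling). These rested on single libraries. The nuclear count was 6521, 99 and 68 without JQ1-VHL replicates 1, 2 and 3, and 390 and 462 without IBET151-VHL replicates 1 and 3. The cytoplasmic count was 363, 51 and 79 without JQ1-VHL replicates 1, 2 and 3. Fitted on these 6 libraries alone, limma called 0 genes in either fraction, where 1771 and 651 genes had an unadjusted p under 0.05 and edgeR called 1271 and 227 in all 14 libraries. JQ1 and IBET151 differed in 0 genes by limma, edgeR and DESeq2 in every table, with 191 nuclear and 429 cytoplasmic T>C genes and 107 and 66 genes of all reads at an unadjusted p under 0.05. In the nucleus limma called 2239 T>C and 277 all-read genes with weights per library. It called 1 and 3456 with a replicate block, which pairs IBET151 across runs. The difference was -0.44 (95% interval -1.92 to 1.04) for nuclear T>C reads of HEXIM1 and -0.31 (95% interval -1.99 to 1.37) for MYC. The summed T>C value differed from that of JQ1 in JQ1-VHL by -0.98 (95% interval -2.31 to 0.34) in the nucleus and -0.95 (-1.27 to -0.63) in the cytoplasm, and from that of IBET151 in IBET151-VHL by -2.45 (-3.93 to -0.96) and -1.45 (-1.81 to -1.10). It differed between JQ1 and IBET151 by -0.60 (-2.09 to 0.88) and -0.33 (-0.68 to 0.029). Between JQ1-VHL and IBET151-VHL it differed by 0.86 (-0.47 to 2.18) and 0.18 (-0.14 to 0.49).

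In all reads of the cytoplasm, BRD2, HEXIM1 and MYC were among the genes lower under the VHL compounds than under their parents. There 6 genes were higher and 521 lower in JQ1-VHL than in JQ1, and 4 higher and 982 lower in IBET151-VHL than in IBET151. The JQ1-VHL count was 259 and 338 without JQ1 replicates 1 and 2, and 268 and 334 without JQ1-VHL replicates 1 and 3. In the nucleus the counts were 19 and 24 and 5 and 73. Median-ratio scaling gave 79 higher and 502 lower, and 95 and 495, there, and a replicate block, which pairs JQ1-VHL with JQ1, gave 198 and 559 for JQ1-VHL. The nuclear JQ1-VHL count was 87, 20 and 12 without JQ1 replicates 1, 2 and 3, and 21, 22 and 0 without JQ1-VHL replicates 1, 2 and 3. More genes were higher than lower without JQ1-VHL replicate 1, JQ1 replicate 2 or JQ1 replicate 3. The nuclear IBET151-VHL count was 11 and 33 without IBET151-VHL replicates 1 and 3. JQ1-VHL and IBET151-VHL differed in 2 cytoplasmic genes, EPC1 being 1 of them, and in 0 nuclear genes by limma, edgeR and DESeq2 (136 at an unadjusted p under 0.05, and 8 with a replicate block). The cytoplasmic count was 1 without JQ1-VHL replicate 1 and 0 without any other 1 library of the 2 groups.

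The nuclear and cytoplasmic effects of each drug were then set against each other in 1 fit of all 28 libraries, to ask whether new RNA was kept back in the nucleus. KLF6, a short-lived factor, had 1076 ± 266 nuclear T>C units (SD, n = 3) in IBET151-VHL and 11.7 ± 3.36 cytoplasmic units, and its nuclear change exceeded its cytoplasmic change by 3.91 ± 0.74 (adjusted p = 1.28e-04), and by 2.87 in JQ1-VHL, which did not pass with edgeR or only the groups compared. RNPS1, an RNA-binding protein of export and splicing, had 182 ± 79.3 and 0.864 ± 1.50 units in IBET151-VHL (3.61 ± 0.87, adjusted p = 0.00158). HEXIM1 differed by 2.24 ± 0.83 (adjusted p = 0.0379), and did not pass with edgeR, DESeq2 or a pseudocount of 5, without run D, or without DMSO nuclear replicate 1 (1.99), IBET151-VHL nuclear replicates 2 or 3 (1.88 and 2.18), DMSO cytoplasmic replicates 1 or 2 (2.34 and 2.01) or IBET151-VHL cytoplasmic replicates 1 or 3 (2.06 and 2.03). The histone gene H2BC11 differed by 4.61 in JQ1-VHL. In T>C reads 88 genes had a higher and 598 a lower change in the nucleus than in the cytoplasm under JQ1-VHL, 189 and 2863 under IBET151-VHL, 0 and 23 under JQ1, and 2 and 17 under IBET151. The lower calls came from genes with few cytoplasmic T>C reads: all 598 of JQ1-VHL and 2843 of the 2863 of IBET151-VHL had a mean cytoplasmic T>C value under 20. Among the 889 genes at or above 20, 26 were higher and 0 lower under JQ1-VHL, and 92 and 20 under IBET151-VHL, with median differences of 1.06 and 0.95.

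With median-ratio scaling 200 higher and 135 lower genes were called under JQ1-VHL, 1191 and 959 under IBET151-VHL, 0 and 3 under JQ1 and 0 and 0 under IBET151 (382 at an unadjusted p under 0.05). The medians moved from -0.30 to 0.24 and from -1.24 to 0.17 in the VHL compounds. By edgeR 5 higher and 0 lower genes were called under JQ1-VHL and 12 and 10 under IBET151-VHL. The JQ1-VHL count was 986 without JQ1-VHL nuclear replicate 1, 285 without DMSO nuclear replicate 2, 404, 447 and 405 without DMSO cytoplasmic replicates 1, 2 and 3, and 317, 325 and 370 without JQ1-VHL cytoplasmic replicates 1, 2 and 3. More genes were higher than lower without JQ1-VHL nuclear replicate 1. The IBET151-VHL count was 1896 without DMSO nuclear replicate 2. The JQ1 count was 13 and 55 without JQ1 nuclear replicates 1 and 2, 15 and 60 without DMSO nuclear replicates 2 and 3, 10 and 15 without DMSO cytoplasmic replicates 1 and 3, and 12, 9 and 11 without JQ1 cytoplasmic replicates 1, 2 and 3. The IBET151 count was 9 and 39 without DMSO nuclear replicates 2 and 3, and 0 without any 1 cytoplasmic library of DMSO. Of 33 speckle and SR protein genes 0 were higher and 0 lower under JQ1-VHL (0 and 0 adjusted over the list alone, 6 at an unadjusted p under 0.05 and 0 by edgeR), and 1 and 1 under IBET151-VHL (1 and 0 alone). The list's median lay 1.43 and 1.37 above that of all genes, most of which had few cytoplasmic T>C reads (camera, adjusted p = 5.67e-07 and 1.37e-04, or 0.676 and 0.552 with estimated correlation). For the 34 export factors it lay 0.86 and 0.52 above (adjusted p = 0.0111 and 0.159, or 0.72 and 0.775 with estimated correlation). Of these 0 were higher and 0 lower under JQ1-VHL by limma (0 and 0 alone, 8 at an unadjusted p under 0.05 and 0 by edgeR). Of 19 polyadenylated histone genes 4 and 6 were higher in the nucleus (6 and 6 alone). In all reads 0 genes passed in JQ1, JQ1-VHL and IBET151 by limma or edgeR (157, 316 and 196 at an unadjusted p under 0.05), and 1 gene, FEZF1, named after its values were seen, passed in IBET151-VHL by limma (2 genes without DMSO cytoplasmic replicate 2 or IBET151-VHL cytoplasmic replicate 1), while edgeR did not call FEZF1. With a replicate block 2 higher and 0 lower genes passed in JQ1-VHL and 41 and 303 in IBET151-VHL, and with paired differences between fractions 33 and 11, and 26 and 21. Median-ratio scaling called 53 higher and 4 lower in JQ1-VHL and 107 and 29 in IBET151-VHL. In simulations of JQ1 with 14369 genes of all reads and 11974 T>C genes, 1 of 66 and 0 of 66 genes changed 4-fold in the nucleus alone were recovered.

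In DMSO alone the fractions parted known nuclear and cytoplasmic RNAs, but most ER-translated mRNAs were higher in the nuclear pellet. Nuclear values may thus include RNA outside nuclei. MALAT1, a nuclear noncoding RNA, stood at 38870.1 ± 17987 in nuclear and 2138 ± 938 in cytoplasmic reads (SD, n = 3, 4.15 ± 0.59, adjusted p = 2.50e-07). NEAT1 differed by 3.12, and ERBB2, whose mRNA is translated at the ER, by 3.69 (61124 and 4410.3). The ribosomal protein mRNA RPS12 was lower in the nucleus (-2.28 ± 0.59, adjusted p = 0.00136). In T>C reads FLNA, a cytoskeleton gene, was at 546 ± 381 and 1.94 ± 1.71 (7.56 ± 0.69, adjusted p = 2.90e-15), and HEXIM1 differed by 2.70. Of 14438 genes in all reads 6923 were higher in the nucleus and 79 lower, with a median of 1.26 (8680 higher and 1197 lower and a median of 1.03 with median-ratio scaling, and 11767 and 53 higher and lower with a replicate block, which pairs the fractions here), and of 12059 in T>C reads 11291 and 3. Of 6 nuclear-retained RNAs 6 were higher (6 adjusted over the list alone), at 1.67 relative to all genes (camera, adjusted p = 0.00267, 0.829 with estimated correlation), and of 42 ER-translated mRNAs 35 (36 alone). Of 77 ribosomal protein genes 9 were lower (1 alone), with a median of -2.39 relative to all genes (adjusted p = 2.31e-38, 0.829 with estimated correlation). In T>C reads 33 of 33 speckle and SR protein genes and 32 of 34 export factors were higher in the nucleus (33 and 33 alone), such as the speckle core gene SRRM2 (6.57) and NXF1 (5.19).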

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

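The comparison of cytoplasmic T>C shares between runs of library numbers was chosen only after the shares were seen.

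The test of the nuclear minus the cytoplasmic drug effect brought up these results. In T>C reads the effects differed for 23 genes under JQ1, 686 under JQ1-VHL, 19 under IBET151 and 3052 under IBET151-VHL. Leaving out 1 library at a time gave 9 to 60, 285 to 1002, 0 to 39 and 1896 to 3558. HEXIM1 fell less in the nucleus than in the cytoplasm under IBET151-VHL by 2.24 ± 0.83 log2 units (SE, limma, adjusted p = 0.0379). It averaged 70.2 ± 34.9 in nuclear T>C reads (DMSO 499 ± 151; SD, n = 3) and 1.29 ± 1.13 in cytoplasmic ones (DMSO 75.5 ± 22.4), and the call ended without any 1 of 7 of the 12 libraries (1.88 to 2.34), without run D (2.39), and with edgeR (adjusted p = 0.167), DESeq2 (0.0503) or a pseudocount of 5 (0.84). In all reads 1 gene differed without a block, FEZF1 under IBET151-VHL (344 with a replicate block, 47 with paired fractions), chosen after its values were seen, with a fitted difference of 6.37 ± 1.08 (adjusted p = 0.00421). Its nuclear value was 40.5 ± 6.91, against 0 in all 3 DMSO libraries, and its cytoplasmic value 1.35 ± 2.33, against 2.50 ± 0.770 in DMSO, so no fold is given. edgeR did not call it (adjusted p = 0.145, range over its alternatives 6.00e-10 to 0.145).

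The first pattern weighed is the larger T>C fall in the nucleus than in the cytoplasm for most genes called under the VHL compounds. New transcripts leaving the nucleus while synthesis stops would lower nuclear values most. Among the 889 genes with a mean cytoplasmic T>C value of 20 or more this was not seen. There edgeR put the nuclear change above the cytoplasmic one, by a median of 1.21 under JQ1-VHL and 1.12 under IBET151-VHL. A change in the RNA yield of a fraction would shift these medians and was not measured, so they cannot decide on this explanation. In limma the medians there were 1.06 and 0.95, and the lower calls came almost wholly from genes below 20, so a floor of low cytoplasmic values is a candidate explanation that these tests met. Nuclear retention of new RNA stays open as a hypothesis for the genes above 20, since the offset between fractions is per RNA mass and a change in the RNA yield of a fraction was not measured.

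The second pattern is the low T>C share of 2.25% and 1.94% in nuclear replicate 3 of DMSO and JQ1, 0.314 and 0.315 of the mean of the other replicates. Weaker labelling, or weaker calling in their run, would lower a cytoplasmic share too, as each culture gave both fractions, but replicate 3 was at 0.934 and 0.952 of the others there, the lowest of each group whichever numbers pair, which argues against it. Fitted as a mixture with the same-numbered cytoplasm, these nuclear libraries held a cytoplasmic share of 0.480 and 0.431, and every other nuclear library of the groups with 3 replicates -0.162 to 0.145, so cytoplasmic RNA in the nuclear fraction is a likely part of the cause. It leaves a share of 4.09% and 3.74% predicted and a lower one seen, and what lowers it further stays open. No biological explanation was tested, since replicates of 1 group have none in the design.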

How the results depend on the processing

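The main fits and the alternatives other than 4 were set before the data were examined. Chosen after seeing the data were the tests without the libraries of run D (the last run of library numbers, holding replicate 3 of DMSO and JQ1 in both fractions), with nuclear numbers 2 and 3 alone, with median-ratio scaling and a replicate block together, without genes of constant T>C share, and on the other splits. Of 572 counts of called genes under an alternative, 333 stayed within 1.5 times the main count with the same balance of higher and lower genes, 88 were smaller, 117 larger and 34 turned the balance. Of 1883 changes of single genes 1773 kept direction and side of 0.05, 57 lost the call, 43 gained one and 10 turned. Of 116 list tests 83 kept their side of 0.05, 29 lost a call and 4 gained one, and of 144 library levels 138 kept theirs. Except where a smaller set of genes or libraries or a removed shift is named, the cause was not tested. In what follows v stands for against and compounds without it are set against DMSO. T>C stands for T>C reads, the interaction is the nuclear minus the cytoplasmic effect, and values in brackets are counts of called genes.

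A pseudocount of 0.5 gave fewer in nuclear T>C for JQ1 (185) and IBET151 (97), cytoplasmic T>C for JQ1 (682) and IBET151 (238) and the T>C interaction for JQ1 (6), JQ1-VHL (311), IBET151 (0) and IBET151-VHL (1959). It gave more in cytoplasmic T>C for JQ1-VHL v IBET151-VHL (305). A pseudocount of 5 gave fewer in nuclear T>C for JQ1-VHL v IBET151-VHL (189), cytoplasmic T>C for JQ1-VHL v IBET151-VHL (5) and cytoplasmic all reads for JQ1-VHL v IBET151-VHL (1). It gave more in nuclear T>C for JQ1 (876) and IBET151 (413), cytoplasmic T>C for JQ1 (2531) and IBET151 (1298), the T>C interaction for JQ1 (228), JQ1-VHL (2347), IBET151 (100) and IBET151-VHL (6282), nuclear all reads for JQ1 (34) and IBET151 (30) and the all-read interaction for JQ1-VHL (14). It turned the balance in nuclear all reads for JQ1-VHL v JQ1 (56, 30 higher) and the all-read interaction for IBET151-VHL (20, 8 higher). Testing without a filter, so more genes, gave fewer in cytoplasmic T>C for JQ1-VHL v IBET151-VHL (106), nuclear all reads for JQ1 (6), IBET151 (2) and IBET151-VHL v IBET151 (40) and cytoplasmic all reads for JQ1-VHL v IBET151-VHL (1). It turned the balance in nuclear all reads for JQ1-VHL (263, 132 higher) and JQ1-VHL v JQ1 (39, 24 higher). A minimum 5 times as high, so fewer genes, gave fewer in cytoplasmic T>C for JQ1 (411), JQ1-VHL (1711), IBET151 (146), IBET151-VHL (1732), JQ1-VHL v JQ1 (1485) and IBET151-VHL v IBET151 (1697), the T>C interaction for JQ1-VHL (428) and IBET151 (8) and the all-read interaction for IBET151-VHL (0). It gave more in cytoplasmic T>C for JQ1-VHL v IBET151-VHL (352) and nuclear all reads for JQ1 (20) and IBET151 (28).

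edgeR gave fewer in nuclear T>C for JQ1 (191), IBET151 (35) and JQ1-VHL v JQ1 (960), cytoplasmic T>C for JQ1 (722) and IBET151 (101), the T>C interaction for JQ1 (0) and IBET151 (0) and cytoplasmic all reads for JQ1-VHL v IBET151-VHL (1). It gave more in nuclear all reads for JQ1 (18) and JQ1-VHL v JQ1 (65). It turned the balance in the T>C interaction for JQ1-VHL (5, 5 higher) and IBET151-VHL (22, 12 higher) and the all-read interaction for IBET151-VHL (1, 0 higher). DESeq2 gave fewer in nuclear T>C for IBET151 (85), cytoplasmic T>C for JQ1 (520) and IBET151 (112) and the T>C interaction for JQ1 (0) and IBET151 (0). It gave more in nuclear T>C for JQ1-VHL v IBET151-VHL (2627), nuclear all reads for JQ1 (23) and JQ1-VHL v JQ1 (84) and cytoplasmic all reads for JQ1 (1048), IBET151 (601) and JQ1-VHL v IBET151-VHL (26). It turned the balance in the T>C interaction for JQ1-VHL (65, 65 higher) and IBET151-VHL (69, 48 higher) and the all-read interaction for IBET151-VHL (6, 2 higher). Fitting only the groups compared, with fewer libraries, gave fewer in nuclear T>C for JQ1-VHL v JQ1 (418) and JQ1-VHL v IBET151-VHL (0), cytoplasmic T>C for JQ1-VHL v IBET151-VHL (0), the T>C interaction for JQ1 (6), JQ1-VHL (349) and IBET151 (0), nuclear all reads for IBET151 (1) and cytoplasmic all reads for JQ1 (142), JQ1-VHL (987), IBET151 (145), IBET151-VHL (1263) and JQ1-VHL v IBET151-VHL (0). They gave more in nuclear T>C for JQ1 (490), nuclear all reads for IBET151-VHL v IBET151 (135) and the all-read interaction for JQ1-VHL (2). They turned the balance in nuclear all reads for JQ1 (1, 1 higher) and JQ1-VHL v JQ1 (17, 13 higher) and the all-read interaction for IBET151-VHL (3, 1 higher). Weights per library gave fewer in cytoplasmic all reads for JQ1 (296), JQ1-VHL (895) and IBET151 (208). They gave more in nuclear T>C for JQ1 (6360), IBET151 (2186), JQ1 v IBET151 (2239) and JQ1-VHL v IBET151-VHL (7109), the T>C interaction for JQ1 (378) and IBET151 (150), nuclear all reads for JQ1 (10973), JQ1-VHL (6100), IBET151-VHL (8159), IBET151-VHL v IBET151 (2702), JQ1 v IBET151 (277) and JQ1-VHL v IBET151-VHL (2279), cytoplasmic all reads for JQ1-VHL v JQ1 (1261), IBET151-VHL v IBET151 (1689) and JQ1-VHL v IBET151-VHL (37), the all-read interaction for JQ1 (1827), JQ1-VHL (1301) and IBET151 (36) and the DMSO fractions in all reads (12199). They turned the balance in the T>C interaction for JQ1-VHL (2380, 1239 higher), nuclear all reads for IBET151 (2660, 697 higher) and JQ1-VHL v JQ1 (6319, 4286 higher) and the all-read interaction for IBET151-VHL (3304, 407 higher).

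Median-ratio scaling, which removes a shift shared by all genes, gave fewer in nuclear T>C for JQ1-VHL (1625), IBET151-VHL (4907), JQ1-VHL v JQ1 (404), IBET151-VHL v IBET151 (1906) and JQ1-VHL v IBET151-VHL (623), cytoplasmic T>C for JQ1-VHL (880), IBET151-VHL (2032), JQ1-VHL v JQ1 (219) and IBET151-VHL v IBET151 (816) and the T>C interaction for JQ1 (3) and IBET151 (0). It gave more in nuclear all reads for JQ1 (618), JQ1-VHL (1283), IBET151-VHL (2104), JQ1-VHL v JQ1 (581), IBET151-VHL v IBET151 (590) and JQ1-VHL v IBET151-VHL (1), cytoplasmic all reads for IBET151 (633) and JQ1-VHL v IBET151-VHL (9) and the all-read interaction for JQ1-VHL (57) and IBET151-VHL (136). It turned the balance in cytoplasmic T>C for JQ1 (37, 20 higher) and IBET151 (22, 12 higher), the T>C interaction for JQ1-VHL (335, 200 higher) and IBET151-VHL (2150, 1191 higher) and nuclear all reads for IBET151 (574, 251 higher). In nuclear T>C reads it turned HEXIM1 in IBET151-VHL to 0.092 (adjusted p = 0.832, range over its alternatives 1.26e-08 to 0.832) and NXF1 to 1.69 (adjusted p = 0.00299, range over its alternatives 0.00105 to 0.995) in JQ1-VHL and 2.63 (adjusted p = 2.13e-05, range over its alternatives 7.06e-06 to 0.93) in IBET151-VHL. NXF1 in IBET151-VHL v IBET151 turned to 0.53 (adjusted p = 0.307, range 5.57e-06 to 0.307). Scaling and block together left these 4 values at 0.092, 1.69, 2.63 and 0.67. Median-ratio scaling and a replicate block together gave fewer in nuclear T>C for JQ1-VHL (2117), IBET151-VHL (5382), JQ1-VHL v JQ1 (755) and IBET151-VHL v IBET151 (2185) and cytoplasmic T>C for JQ1-VHL (892), IBET151-VHL (2065), JQ1-VHL v JQ1 (265) and IBET151-VHL v IBET151 (790). Both together gave more in nuclear all reads for JQ1 (1471), JQ1-VHL (2618), IBET151-VHL (3879), JQ1-VHL v JQ1 (1506), IBET151-VHL v IBET151 (1673) and JQ1-VHL v IBET151-VHL (19) and cytoplasmic all reads for JQ1 (1168), IBET151 (1367), IBET151-VHL (3131), JQ1-VHL v JQ1 (888) and JQ1-VHL v IBET151-VHL (22). Both together turned the balance in nuclear T>C for JQ1 (376, 207 higher) and IBET151 (280, 166 higher), cytoplasmic T>C for JQ1 (49, 31 higher) and IBET151 (32, 24 higher) and nuclear all reads for IBET151 (1469, 666 higher).

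The replicate block gave more in nuclear T>C for JQ1 (522), IBET151 (265), JQ1-VHL v JQ1 (3175), JQ1 v IBET151 (1) and JQ1-VHL v IBET151-VHL (2809), nuclear all reads for JQ1 (1538), JQ1-VHL (3757), IBET151 (818), IBET151-VHL (6630), JQ1-VHL v JQ1 (757), IBET151-VHL v IBET151 (9443), JQ1 v IBET151 (3456) and JQ1-VHL v IBET151-VHL (8), cytoplasmic all reads for JQ1 (948) and IBET151 (560), the all-read interaction for JQ1-VHL (2) and the DMSO fractions in all reads (11820). The same block turned the balance in the all-read interaction for IBET151-VHL (344, 41 higher). Replicate numbers paired the samples only where the correlation check above held. Elsewhere libraries shared a number only, or IBET151 left 2 pairs. By library number IBET151 replicates 1 and 2 lie in the runs of replicates 2 and 3 of the VHL compounds. This block and permutation within replicate number thus match IBET151 across runs. As a hint from the data, every sample of both groups did correlate best with its own number in the cytoplasmic T>C reads of all pairs of groups with 3 numbers but JQ1 with JQ1-VHL (5 of 6 samples), and in the nuclear ones but for JQ1-VHL (4 of 6) and IBET151-VHL (5 of 6) with DMSO. Of single genes the block changed the call of HEXIM1 in cytoplasmic all reads of JQ1 and of NEAT1 in nuclear all reads of IBET151 and of both VHL compounds, and it changed no other call of a gene or list. Paired differences between fractions, a block per culture, gave fewer in the T>C interaction for IBET151 (7). They gave more in the all-read interaction for JQ1-VHL (44), IBET151 (1) and IBET151-VHL (47). The run of library numbers as a block gave more in nuclear T>C for JQ1 (1404), IBET151 (665), JQ1-VHL v JQ1 (7466) and JQ1-VHL v IBET151-VHL (5483), cytoplasmic T>C for JQ1-VHL v IBET151-VHL (323), the T>C interaction for JQ1-VHL (1087), nuclear all reads for JQ1 (5063), JQ1-VHL (5909), IBET151-VHL (8555), JQ1-VHL v JQ1 (1269), IBET151-VHL v IBET151 (2767) and JQ1-VHL v IBET151-VHL (139), cytoplasmic all reads for JQ1 (1606), JQ1-VHL (3336), IBET151 (890), IBET151-VHL (3567), JQ1-VHL v JQ1 (1069), IBET151-VHL v IBET151 (1483) and JQ1-VHL v IBET151-VHL (19) and the all-read interaction for JQ1-VHL (7) and IBET151 (3). The run as a block turned the balance in nuclear all reads for IBET151 (3214, 276 higher) and the all-read interaction for IBET151-VHL (40, 11 higher). With it MALAT1 in nuclear T>C reads turned to -1.03 (adjusted p = 0.0235, range 0.0107 to 0.899) in JQ1-VHL. In IBET151-VHL it turned to -1.08 (adjusted p = 0.0164, range 2.27e-04 to 0.96).

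Permuting the library levels within replicate number, as a block, gave the VHL compounds against their parents -1.63 (nuclear T>C sum, log2, exact permutation p = 0.0625), -1.15 (cytoplasmic sum, p = 0.0625), -2.76 (nuclear share in points, p = 0.125) and -0.301 (cytoplasmic share, p = 0.0625). The smallest p these blocks allow is 0.0625, so none of these can pass 0.05. For all drugs the nuclear share changed by -2.52 points (exact permutation p = 0.04), and by -3.94 without run D (p = 0.0303). Without the 10 genes of highest mean value all 36 library comparisons kept direction and side of 0.05, as without genes of constant T>C share.

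Leaving out run D, so fewer libraries, gave fewer in nuclear T>C for JQ1 (104) and JQ1-VHL v JQ1 (883), cytoplasmic T>C for JQ1 (590) and JQ1-VHL v IBET151-VHL (112), the T>C interaction for JQ1 (9), nuclear all reads for IBET151-VHL (286), cytoplasmic all reads for JQ1-VHL v IBET151-VHL (1) and the DMSO fractions in all reads (4246). Without run D the fit gave more in the T>C interaction for IBET151 (30) and cytoplasmic all reads for JQ1-VHL (2452) and IBET151 (547). Without run D the fit turned the balance in nuclear all reads for JQ1 (1, 1 higher), JQ1-VHL (123, 72 higher) and JQ1-VHL v JQ1 (7, 7 higher) and the all-read interaction for IBET151-VHL (4, 1 higher). Nuclear numbers 2 and 3 alone, so fewer libraries, gave fewer in nuclear T>C for JQ1 (17), JQ1-VHL (1800), IBET151 (6), JQ1-VHL v JQ1 (8) and IBET151-VHL v IBET151 (6282) and nuclear all reads for IBET151 (0) and IBET151-VHL v IBET151 (50). They gave more in the T>C interaction for JQ1 (52), nuclear all reads for JQ1 (33), JQ1-VHL (909), IBET151-VHL (2875) and JQ1-VHL v JQ1 (97), the all-read interaction for IBET151-VHL (4) and the DMSO fractions in all reads (11201). Of 284 counts with 1 library left out 178 stayed within 1.5 times the main count with its balance, 80 were smaller, 13 larger and 13 turned. Their ranges were, in nuclear T>C for JQ1-VHL v JQ1 (105 to 2579), JQ1-VHL v IBET151-VHL (68 to 6521), JQ1 (90 to 389), JQ1-VHL (3643 to 8103) and IBET151 (34 to 141), cytoplasmic T>C for JQ1-VHL v IBET151-VHL (51 to 363), JQ1 (513 to 1154) and IBET151 (191 to 409) and the T>C interaction for JQ1 (9 to 60), JQ1-VHL (285 to 1002), IBET151 (0 to 39) and IBET151-VHL (1896 to 3558). For all reads they were, in nuclear all reads for JQ1-VHL v JQ1 (0 to 87), IBET151-VHL v IBET151 (1 to 84), JQ1 v IBET151 (0 to 1), JQ1 (2 to 34), JQ1-VHL (137 to 412), IBET151 (3 to 14) and IBET151-VHL (279 to 966), cytoplasmic all reads for JQ1-VHL v JQ1 (259 to 526), IBET151-VHL v IBET151 (385 to 806), JQ1-VHL v IBET151-VHL (0 to 1), JQ1 (273 to 953), JQ1-VHL (905 to 2083) and IBET151 (53 to 532) and the all-read interaction for IBET151-VHL (1 to 2). Library levels ranged from -1.90 to -1.38 (log2 nuclear T>C sum, VHL compounds v parents), from -3.59 to -2.40 points (nuclear share, the same) and from -4.05 to -1.17 (nuclear share, all drugs). Of 855 changes of single genes 35 lost a call, 1 gained one and 0 turned. Where IBET151 was left with 1 library, it was assumed to vary like the other groups.

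Of 29 list tests, 24 of them called, 11 kept their side of 0.05 with an estimated correlation and 18 lost a call. With fry, which compares a list with no other genes, 18 kept their side, 9 lost and 2 gained one. With median-ratio scaling 25 kept it, 2 lost a call and 2 gained one. Scaling by Drosophila reads and leaving out mitochondrially encoded genes were not run, as the tables hold neither. Depth was not varied, and in all reads replicates differed by 28.7 to 331 times counting noise (chi-squared per degree of freedom).

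Each comparison of 3 against 3 libraries was set against the other splits of the same libraries. There are 10 splits, which cannot give a share under 0.05. For 17 comparisons, with 1 to 11294 genes in the real split, the highest other split called 0 genes, so 1 of 10 splits called as many. The real split and the highest other gave 291 against 5 genes for JQ1 in nuclear T>C reads, 192 against 2 for JQ1-VHL v IBET151-VHL in cytoplasmic T>C reads, 601 against 112 for JQ1 in cytoplasmic all reads, and 284 against 1, 656 against 15 and 43 against 3 for JQ1-VHL, IBET151-VHL and JQ1-VHL v JQ1 in nuclear all reads, with 1 of 10 splits as large in each. Between JQ1-VHL and IBET151-VHL in nuclear T>C reads it was 1326 against 4227, with 2 of 10 as large. The higher split sets replicate 1 of JQ1-VHL with replicates 1 and 3 of IBET151-VHL, and its count, several times the real one, points to a structure of the samples. In nuclear all reads of JQ1 it was 10 against 193, with 3 of 10 as large, where the highest put DMSO replicate 1 with JQ1 replicates 1 and 2, again a structure of the samples. Where replicate numbers pair the samples, every other split that parts all 3 pairs, as the real one does, called 0 genes, while the rest keep 2 pairs together. For 3 comparisons with 0 genes (JQ1-VHL v IBET151-VHL in nuclear all reads, and the all-read interactions of JQ1 and JQ1-VHL) 10 of 10 splits called as many.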

Other observations

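The tests below were set before their results were seen, except the listing of genes of constant T>C share.

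Long genes lost less new RNA under the VHL compounds. Genes of 200 kb or more lay above genes under 20 kb by a median of 0.731 log2 units in JQ1-VHL and 0.978 in IBET151-VHL (nuclear T>C reads), by 0.266 in JQ1 (0.243 inside 10 bins of equal mean value, 7 of them above 0), and by -0.010 in IBET151. Inside such bins the VHL difference was 0.622 and 0.842 (9 of 10 bins above 0 in each). The mean covered drug libraries too, so the bins did not match the level in DMSO. A low level of long genes thus stays open. Priming inside introns of nuclear RNA is argued against, since the cytoplasm gave 0.796 and 0.877 without bins and 0.803 and 0.845 inside them (10 of 10 above 0). Polymerases released before the drug may explain it only if they reached gene ends in the labelled last 60 min of 3 h. Their timing was not tested. A difference above 1 was predicted and not reached, so this cannot be told from slower turnover or another property of long genes. Background conversions, which weigh more where new RNA is low, stay open too without an unlabelled library. Genes are not independent replicates, so no p is given.

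The 21 genes of constant T>C share in the cytoplasm had a median ratio of nuclear shares, VHL compounds to DMSO, of 0.761 (0.370 to 1.06), and 10826 other genes one of 0.264.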
